A study of Homo sapiens with 9 samples.

How the data were processed

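RNA was measured in 9 samples of primary human hepatic stellate cells, 3 each with ABHD17B siRNA 1, ABHD17B siRNA 4 and the non-targeting control siRNA 5, 3 days after transfection. Per the labels, the cells were kept in DMEM with 10% FBS and 1% antibiotics, transfected with Dharmafect-1, and RNA with an integrity number above 9 was made into stranded, poly(A)-selected libraries read as pairs of 150 nt. The deposited files hold raw counts per Ensembl gene, 1 file per sample, and the values are whole numbers without normalization. The aligner, the counting tool and the genome build used by the authors are not given in the sources used here. The 58735 gene identifiers were those of GENCODE release 29 (GRCh38), from which coordinates and transcript sequences were taken, and 58207 had a symbol. Total counts ran from 31842621 to 41702571 per sample, and 33039 genes had a count in any sample.

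Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15, smallest group 3), which left 17750. Counts were scaled by TMM and fitted in a single model with a mean per group by edgeR's quasi-likelihood test with robust dispersion (edgeR 4.0.16, R 4.3.3). The contrasts were each siRNA against the control, both siRNAs together against the control, and siRNA 1 against siRNA 4, each two-sided and adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. A gene was called alike when it passed with each siRNA in the same direction. The biological coefficient of variation was 12.6%. The covariance of the fold changes was set beside 20 simulations of unchanged groups that share their controls.

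The groups, contrasts, 37 gene lists (876 genes, 1 unmatched), tests and alternatives were fixed before the data were examined. The 35 lists with at least 5 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01, prior count 2 on log2 CPM), adjusted over the lists. The lists of the target family (3 tested genes) and of macrophage and leukocyte markers (4) were too small. Camera with an estimated correlation and fry served as alternatives. Members called were also counted after an adjustment over the list alone.

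Named genes followed a rule. It took ABHD17B, ABHD17A and ABHD17C always. For each siRNA it took the 10 highest and 10 lowest log2 fold changes, and between the siRNAs 5 of each, among genes that passed, with an average log2 CPM of at least 1 and groups that did not overlap, passing over clone names. For genes changed alike it took the 12 highest and 12 lowest mean fold changes. It further took up to 4 members per list with the smallest adjusted p over both siRNAs together, and whatever their values a fixed set with COL1A1, COL1A2, COL3A1, ACTA2, TAGLN, FN1, TIMP1, LOX, PDGFRB, CCN2 and TGFB1. Some genes that the rule takes are not given in the text. Genes outside the rule are named as chosen after their values were seen.

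A search for 7-base words was not among the choices made before the data were examined. For each gene the protein-coding transcript with the longest 3′ UTR was taken, its coding sequence and 5′ UTR were searched likewise, regions under 50 nt were left out, and fold changes were corrected for log length, GC content and their squares. Words in at least 30 genes were ranked by z over 14093 genes with a searched 3′ UTR (median length 1384 nt), and standard errors of site-number medians came from 1000 bootstrap resamples. Ratios of counts carry exact Clopper-Pearson intervals, which cover counting error only.

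Alternatives were DESeq2 size factors, upper-quartile scaling, no count filter, a filter of 1 CPM in 3 samples, DESeq2 1.42.0, limma-voom, fits of the compared groups alone, replicate number as a block, a test against a fold of 1.2, an adjusted p of 0.01, a fold of 2 with both siRNAs, and leaving out each sample in turn. The fit was tested on simulated data with 200 changed genes for siRNA 1, for siRNA 4 and between the siRNAs. It recovered 33, 31 and 34 of 67 genes changed 1.5-fold, 44, 45 and 44 of 67 changed 2-fold and 49, 54 and 56 of 66 changed 4-fold, with 7.35%, 6.47% and 6.29% false calls. Only 200 of 17750 genes were changed there, while 24.2% to 31.7% were called in the data, so these rates need not hold for it. Results were listed for a closer look where a gene list differed between the siRNAs or a named gene was called in opposite directions, while groups of 3 samples were not tested for outliers. Summaries and figures used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No sample was left out, and splicing and sequence variants were not analysed here.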

Results

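Transcript levels were measured by stranded, poly(A)-selected RNA sequencing in primary human hepatic stellate cells, the vitamin A-storing cells of the liver that turn into matrix-producing myofibroblasts in fibrosis. The cells, from a commercial source, were transfected for 3 days with ABHD17B siRNA 1, with ABHD17B siRNA 4 or with the non-targeting control siRNA 5. ABHD17B is a serine hydrolase of the ABHD17 family, which removes palmitate from proteins. Each of the 3 groups held 3 samples, 9 in all, and the labels state the purpose only as depletion of ABHD17B mRNA with a pair of siRNAs. The total counts ranged from 31842621 (control replicate 1) to 41702571 (siRNA 1 replicate 3) per sample. Of 58735 annotated genes, 17750 passed the count filter and were tested. The fibronectin gene FN1 took the largest share of counts in each of the 9 samples, from 2.56% to 3.37%.

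The groups separated from each other on the first pair of principal components, which held 34.7% and 22.3% of the variance. Correlations across genes were 0.984 to 0.988 within groups and 0.965 to 0.978 between groups, where genes are not independent replicates. The number of genes with a count was 24077 to 24333 in the control samples and 24838 to 25311 in the siRNA-treated samples. Counts of mitochondrially encoded genes took 2.42% to 3.00% of each library. Whether the samples of a group come from separate cultures or donors is not given in the sources used here, so the p-values measure the spread between these samples, which may be technical. Below, fold changes are on the log2 scale and ± beside them is the standard error of the fit with n = 3 per group, while ± beside CPM (counts scaled to a common library size) is the SD over the 3 samples.

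ABHD17B mRNA fell with both siRNAs. The gene (ENSG00000107362) lies on the minus strand of chromosome 9 from 71862452 to 71910931 in the GRCh38 build. Its level was 9.21 ± 2.10 CPM in the control, 0.900 ± 0.174 CPM with siRNA 1 and 1.45 ± 0.200 CPM with siRNA 4 (n = 3 each), behind which stand 259 to 438 counts per control sample, 31 to 42 with siRNA 1 and 47 to 68 with siRNA 4. The log2 fold change was -3.36 ± 0.22 with siRNA 1 (adjusted p = 5.27e-07 in edgeR's quasi-likelihood test) and -2.67 ± 0.21 with siRNA 4 (adjusted p = 3.99e-06), so that 9.77% and 15.7% of the control level remained, and every treated sample lay below every control sample. The difference between the siRNAs, -0.69 ± 0.23, missed the threshold with an adjusted p of 0.0509. For ABHD17B it passed without a count filter (0.0332), with DESeq2 (0.0432), with upper-quartile scaling (0.0450), with replicate number as a block (0.0450), with a filter of 1 CPM (0.0451) and without control replicate 2 (0.0404), siRNA 1 replicate 1 (0.0440) or control replicate 3 (0.0472). Under the other alternatives its adjusted p was 0.0505 to 0.170.

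The close relatives of the target behaved differently from it. ABHD17A (ENSG00000129968; chromosome 19, 1876810 to 1885547) rose with both siRNAs, by 0.59 ± 0.12 (adjusted p = 0.00308) and 0.61 ± 0.12 (adjusted p = 0.00288), from 52.2 ± 8.90 CPM in the control to 78.3 ± 8.37 and 79.9 ± 8.03 CPM. ABHD17C (ENSG00000136379; chromosome 15, 80679684 to 80755621) had log2 fold changes of 0.03 ± 0.12 and -0.08 ± 0.12, with adjusted p values of 0.902 and 0.710. Other enzymes that remove palmitate from proteins went both ways, 3 of 9 higher and 2 lower (3 and 2 adjusted over the list alone) with siRNA 1 and 1 of 9 higher and 3 lower (2 and 3 adjusted over the list alone) with siRNA 4. Among them ABHD10 fell by 0.88 and 0.99 on the log2 scale. Over both siRNAs together the called members of that list were 1 higher and 2 lower, which became 3 higher and 2 lower under upper-quartile scaling. Palmitoyltransferases, which attach the lipid, were 5 of 21 higher and 4 lower (5 and 4 adjusted over the list alone) with siRNA 1 and 3 of 21 higher and 4 lower (3 and 5 adjusted over the list alone) with siRNA 4, and ZDHHC5, which was lower with both, had values of -0.61 and -0.63. Neither list differed as a set from other genes (camera adjusted p = 0.896 and 0.850 with siRNA 1, 0.350 and 0.924 with siRNA 4).

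**Figure D1:**
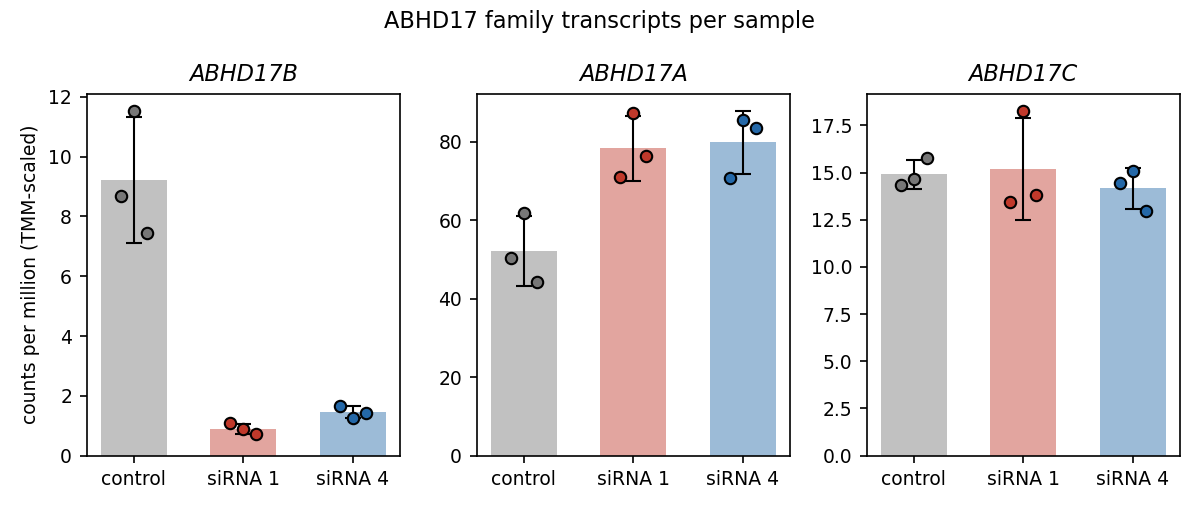
Normalised counts (y axes, CPM, TMM-scaled) of ABHD17B, ABHD17A and ABHD17C in the control, siRNA 1 and siRNA 4 groups. Points are single samples, bars are group means and error bars the SD (n = 3); ABHD17B lay near 0.900 and 1.45 CPM with the siRNAs against 9.21 CPM in the control.

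siRNA 1 against the control asked what changed when the first ABHD17B siRNA was used. KRT6A, SFN and SPINT1 were among the genes that rose most, and the actin-severing CFL2 and the collagen cross-linker LOX were among those that fell most. KRT6A, a keratin of activated epithelia, rose by 6.30 ± 0.30. SFN, the epithelial 14-3-3 sigma protein, rose by 5.80 ± 0.21 to 33.4 ± 5.66 CPM, and the epithelial protease inhibitor SPINT1 by 4.90 ± 0.31 to 40.7 ± 4.72 CPM. CFL2 fell from 101 ± 3.16 to 8.45 ± 0.505 CPM, a log2 fold change of -3.58 ± 0.079 (adjusted p = 1.37e-10). LOX, a lysyl oxidase, fell from 1560 ± 124 to 238 ± 43.6 CPM (-2.71 ± 0.12; adjusted p = 3.59e-08).

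HSH2D, an adaptor protein of blood cells, had 1037 counts over the 3 samples with siRNA 1 against 5 over the 3 control samples, a ratio of 194 (82.9 to 599, exact binomial 95% interval, counting error only). The remaining genes of the 10 with the highest fold changes were CHMP4C, a membrane-scission protein (4.71), the cadherin CDH3 (4.61), the lysosomal membrane protein LAMP3 (4.29), the ubiquitin ligase subunit FBXO2 (4.24), the kinase CDC42BPG (4.16) and the adaptor SH2D3A (4.01). Besides CFL2, LOX and ABHD17B, the 10 lowest held BEX1 (-2.72), the matricellular protein CCN4 (-2.69), the fibroblast membrane protein LRRC15 (-2.61), OSTM1, a subunit of the lysosomal chloride transporter (-2.61), SHCBP1 (-2.54), ZNF804A (-2.53) and the chondroitin synthase CHSY3 (-2.53). The adjusted p of these 20 genes ranged from 1.37e-10 to 9.39e-06, and in each the 3 values of siRNA 1 lay on the same side of all 3 control values. The 7-base word CAGTATT stood in the 3′ UTRs of 5 of these 10 lowest genes, with 3 sites in CFL2, 3 in LOX, 2 in OSTM1 and 1 each in SHCBP1 and CHSY3, and in 0 of the 10 highest. This word was the one that went most with lower expression under siRNA 1 (z = -10.5), and 19.0% of 14093 searched genes held it. It was picked from these same fold changes, so its sites in the lowest genes are no separate support. The 3′ UTRs of CFL2 (6096 nt) and LOX (3548 nt) are also longer than the median of 1384 nt.

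In all, 5629 genes passed an adjusted p of 0.05 with siRNA 1, 2628 higher and 3001 lower, of which 824 and 547 changed at least 2-fold. Upper-quartile scaling turned this balance, with 2969 higher and 2678 lower. The groups did not overlap in 7762 of the 17750 genes, where chance separates 10%.

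Type I interferon response genes, which cells switch on against viral RNA, rose together with siRNA 1. The interferon set had adjusted p = 1.23e-14, and adjusted p = 0.319 with an estimated correlation. Of its genes, 35 of 39 were higher and 0 lower with siRNA 1. Interferon genes adjusted over the list alone were 36 higher and 0 lower. The RNA sensors IFIH1 and DDX60 rose by 1.28 ± 0.11 and 1.26 ± 0.098, and the oligoadenylate synthase relative OASL by 1.71 ± 0.15. The interferon gene IFNB1 itself, chosen after its values were seen, had 9 counts over the 3 samples with siRNA 1, 4 with siRNA 4 and 3 in the control. Of complement and antigen presentation genes, 17 of 23 were higher and 0 lower with siRNA 1. The complement set had adjusted p = 1.25e-05, and adjusted p = 0.333 with an estimated correlation. Complement and antigen genes adjusted over the list alone were 17 higher and 0 lower. Among them were the complement regulators CFI (1.04) and SERPING1 (0.79) and the antigen-presenting HLA-E (0.58).

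Inflammatory genes driven by NF-kappaB fell on balance with siRNA 1. The inflammatory set had adjusted p = 0.000191, and adjusted p = 0.283 with an estimated correlation. Of its genes, 3 of 31 were higher and 13 lower with siRNA 1. Inflammatory genes adjusted over the list alone were 3 higher and 14 lower. The neutrophil attractants CXCL8, CXCL6 and CXCL1 fell by 2.28, 1.90 and 1.26 on the log2 scale, and the cytokine IL6 fell by 1.67. Of senescence and growth arrest genes, which share IL6, CXCL8 and CXCL1 with that list, 3 of 19 were higher and 12 lower with siRNA 1. The senescence set had adjusted p = 0.000661, and adjusted p = 0.283 with an estimated correlation. Senescence genes adjusted over the list alone were 3 higher and 13 lower. The cell cycle inhibitor CDKN2B rose by 1.38 ± 0.072. Of growth factor receptors and ligands of activated stellate cells, 3 of 25 were higher and 13 lower with siRNA 1. The receptor set had adjusted p = 0.00750, and adjusted p = 0.397 with an estimated correlation. Receptor genes adjusted over the list alone were 3 higher and 13 lower. PDGFRB, the receptor through which PDGF drives stellate cell growth, fell from 144 ± 11.2 to 42.3 ± 2.91 CPM, a log2 fold change of -1.77 ± 0.12 (adjusted p = 7.13e-07). Of ribosomal protein genes, 0 of 41 were higher and 6 lower with siRNA 1. The ribosomal set had adjusted p = 0.0189, and adjusted p = 0.794 with an estimated correlation. Ribosomal genes adjusted over the list alone were 0 higher and 4 lower. Of mitochondrially encoded genes, 0 of 13 were higher and 4 lower with siRNA 1. The mitochondrial set had adjusted p = 0.0439, and adjusted p = 0.646 with an estimated correlation. Mitochondrial genes adjusted over the list alone were 0 higher and 6 lower. RPSA had -0.45 and MT-ND4L -0.49.

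Markers of other cell types were also measured with siRNA 1. Of cholangiocyte and epithelial markers, 8 of 10 were higher and 0 lower with siRNA 1. The epithelial set had adjusted p = 9.79e-05, and adjusted p = 0.0533 with an estimated correlation. Epithelial markers adjusted over the list alone were 8 higher and 0 lower. Their summed level was 1852 ± 156 CPM with siRNA 1 against 925 ± 61.9 CPM in the control (SD, n = 3). The biliary keratins KRT19 and KRT7 rose by 1.74 ± 0.094 and 1.33 ± 0.084, and the secreted phosphoprotein SPP1 by 1.37 ± 0.099. Macrophage and leukocyte markers had 4 tested members, too few for the set test, of which 2 were higher with siRNA 1 (2 adjusted over the list alone). These were CSF1R, the receptor of a macrophage growth factor, at 7.22 ± 1.66 against 0.471 ± 0.404 CPM, and the lysosomal glycoprotein CD68 (0.35). Hepatocyte markers were 0 of 11 higher and 1 lower with siRNA 1, and 0 higher and 0 lower with siRNA 4. The hepatocyte set had adjusted p = 0.618 and 0.718. Hepatocyte markers adjusted over the list alone were 0 higher and 0 lower with siRNA 1, and 0 and 0 with siRNA 4.

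siRNA 4 against the control asked the same with the other ABHD17B siRNA. ANKRD1, a mechanosensitive muscle ankyrin protein, fell most, from 358 ± 20.2 to 42.1 ± 2.13 CPM (-3.09 ± 0.076; adjusted p = 4.55e-10). THBD, the thrombomodulin that restrains clotting, rose by 2.59 ± 0.13 to 41.3 ± 5.46 CPM, and ESM1, a secreted endothelial proteoglycan, by 2.11 ± 0.13 to 193 ± 22.3 CPM. MEOX2, a homeobox transcription factor, fell by 2.63 on the log2 scale, and ELOVL4, an elongase of very long fatty acids, fell by 2.40.

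The 10 highest fold changes with siRNA 4 further held LYPD3 (2.98), the neuronal pentraxin NPTX1 (2.47), the endothelin receptor EDNRB (2.42), the sterol reductase TM7SF2 (2.19), ADTRP (2.04), the thrombin inhibitor SERPIND1 (1.98) and the phospholipase PLA2G4C (1.92). SCHIP1 (2.21 ± 0.62; adjusted p = 0.0232) was the weakest of them, with an adjusted p of 0.0616 to 0.0769 when siRNA 4 replicate 3 or any control replicate was left out. The 10 lowest further held ABHD17B, the sodium channel SCN3A (-2.69), GRIP2 (-2.61), LYSMD2 (-2.40), the potassium channel KCND3 (-2.29), TXNDC16 (-2.29) and the thyroid hormone receptor THRB (-2.28). In each of the 20 the 3 values of siRNA 4 lay on the same side of all 3 control values. The word TCCTGAT, which went most with lower expression under siRNA 4 (z = -8.79), stood in the 3′ UTRs of 6 of the 10 lowest (MEOX2, GRIP2, ELOVL4, LYSMD2, TXNDC16 and THRB) and of 1 of the 10 highest (EDNRB), against 13.7% of the searched genes. It too was picked from the fold changes that rank these genes, so these counts are no separate support.

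With siRNA 4, 4607 genes passed the threshold, 2110 higher and 2497 lower, of which 454 and 401 changed at least 2-fold. Under upper-quartile scaling more were higher (2546) than lower (2096). The groups did not overlap in 7459 genes, where chance separates 10%.

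Cholesterol synthesis genes were mostly higher with siRNA 4. The sterol set had adjusted p = 2.03e-08, and adjusted p = 0.267 with an estimated correlation. Of its genes, 17 of 26 were higher and 1 lower with siRNA 4. Sterol genes adjusted over the list alone were 21 higher and 1 lower. INSIG1, which holds back the sterol-sensing transcription factors, rose by 1.32 ± 0.060, and HMGCS1, an early enzyme of the pathway, by 1.05 ± 0.090. Of fatty acid and lipid droplet genes, 11 of 30 were higher and 2 lower with siRNA 4. The fatty acid set had adjusted p = 0.00281, and adjusted p = 0.104 with an estimated correlation. Fatty acid genes adjusted over the list alone were 12 higher and 3 lower. The lipid droplet coat PLIN2 had 0.57 and the acyl-CoA synthetase ACSL4, which went the other way, -1.31. Of lysosome and autophagy genes, 14 of 30 were higher and 2 lower with siRNA 4. The lysosome set had adjusted p = 0.000949, and adjusted p = 0.141 with an estimated correlation. Lysosome genes adjusted over the list alone were 16 higher and 2 lower. The protease CTSL had 0.81 and the sphingomyelinase SMPD1, which went the other way, -1.50. Of hypoxia and glycolysis genes, 1 of 30 were higher and 17 lower with siRNA 4. The hypoxia set had adjusted p = 0.000452, and adjusted p = 0.252 with an estimated correlation. Hypoxia genes adjusted over the list alone were 3 higher and 18 lower. Among them were the lactate dehydrogenase LDHA (-0.92) and the phosphofructokinase PFKP (-0.69).

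Integrated stress response genes serve in part the supply of amino acids. Of them, 1 of 24 were higher and 11 lower with siRNA 4. The stress response set had adjusted p = 0.00221, and adjusted p = 0.434 with an estimated correlation. Stress response genes adjusted over the list alone were 2 higher and 12 lower. The amino acid transporter SLC7A5 fell by 1.68 on the log2 scale. Collagens were 3 of 20 higher and 8 lower with siRNA 1, and 2 higher and 11 lower with siRNA 4. The collagen set had adjusted p = 0.192 and 0.00355, and adjusted p = 0.794 and 0.524 with an estimated correlation. Collagens adjusted over the list alone were 4 higher and 9 lower with siRNA 1, and 3 and 12 with siRNA 4. Endothelial markers were 3 of 11 higher and 1 lower with siRNA 1, and 4 higher and 0 lower with siRNA 4. The endothelial set had adjusted p = 0.327 and 0.0358, and adjusted p = 0.597 and 0.249 with an estimated correlation. Endothelial markers adjusted over the list alone were 3 higher and 1 lower with siRNA 1, and 5 and 1 with siRNA 4. The VEGF receptor KDR had 1.89 with siRNA 4, where the summed endothelial level was 137 ± 2.63 CPM against 122 ± 4.52 CPM in the control. Of epithelial markers, 2 of 10 were higher and 3 lower with siRNA 4. The epithelial set had adjusted p = 0.541. Epithelial markers adjusted over the list alone were 2 higher and 4 lower. These summed to 615 ± 14.3 CPM. Of 4 macrophage and leukocyte markers, CD68 (0.63) was higher with siRNA 4 (1 adjusted over the list alone).

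Both siRNAs together against the control asked what reagents against the same target have in common, and the genes changed alike by both answer it most directly. Cell division genes were lower with either siRNA, as were CAV1, OSMR and ACTA2. The caveolar coat protein CAV1 fell from 797 ± 59.4 CPM to 203 ± 10.6 and 213 ± 4.13 CPM. OSMR, a receptor of the cytokine oncostatin M, fell from 314 ± 10.4 CPM to 76.3 ± 6.06 and 66.5 ± 2.50 CPM. ACTA2, the smooth muscle actin that marks activated stellate cells, fell from 211 ± 15.3 CPM to 85.6 ± 14.2 and 93.1 ± 5.66 CPM, with adjusted p values of 2.58e-06 and 9.33e-06.

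A total of 5515 genes differed between both siRNAs together and the control, 2475 higher and 3040 lower (2939 higher and 2552 lower under upper-quartile scaling). Called in both single comparisons in the same direction were 2508 genes, 1049 higher and 1459 lower, where independent lists of the same sizes would share 312 and 422. Under upper-quartile scaling these were 1287 higher and 1219 lower. Opposite calls came from 242 genes, 117 of them higher with siRNA 1 and 125 higher with siRNA 4, against 726 from independent lists. A change of at least 2-fold with both siRNAs was seen in 346 genes, 185 higher and 161 lower. The covariance of the fold changes across genes was 0.234 ± 0.0969 (jackknife SE over samples, with genes filtered anew each time). Pearson's r across genes was 0.543, where genes are not independent replicates. The counts expected from independent lists do not allow for the shared controls. In simulated data without any change the shared controls alone gave a covariance of 0.0515 (0.0472 to 0.0573 over 20 simulations) and an r of 0.518. They gave 0.15 genes called alike on average (0 to 2), and the same sign in 66.9% of genes against 70.5% observed. With 3 control samples the controls were too few to be divided between the comparisons, so part of the excess may come from them.

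Of genes changed alike, LYPD3 (3.15 with siRNA 1 and 2.98 with siRNA 4), ISLR2 (3.63 and 1.15), THBD (1.67 and 2.59), ALS2CL (3.10 and 0.92), DDIT4L (2.41 and 1.47) and the DNA glycosylase NEIL1 (1.89 and 1.83) were among the 12 highest by mean fold change. A further 4 of them rested on weak calls with siRNA 4. The call of CHMP4C (0.85) was lost without any replicate of siRNA 1, siRNA 4 replicate 1 or 3 or control replicate 1 or 3 (adjusted p up to 0.147), and that of HES2 (1.30) without siRNA 1 replicate 2, siRNA 4 replicate 2 or 3 or control replicate 2 or 3 (up to 0.183). The call of WNT11 (1.46) was lost without siRNA 4 replicate 3 or control replicate 2 or 3 (up to 0.0772), and that of GALNT3 (0.83) without siRNA 4 replicate 1 or 2 or control replicate 1 or 2 (up to 0.0840). The 12 lowest held ABHD17B, SCN3A (-2.42 and -2.69), BEX1 (-2.72 and -1.96), CCN4 (-2.69 and -1.98), CFL2 (-3.58 and -0.82), KCND3 (-2.08 and -2.29), OSMR (-2.04 and -2.24), ANKRD1 (-1.19 and -3.09), TXNDC16 (-1.95 and -2.29), the ubiquitin ligase subunit FBXW11 (-2.47 and -1.66), CHSY3 (-2.53 and -1.54) and CAV1 (-1.97 and -1.90). CAGTATT stood in the 3′ UTRs of 6 of these 12 and TCCTGAT in 5, where both words were picked from the same fold changes.

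**Figure D2:**
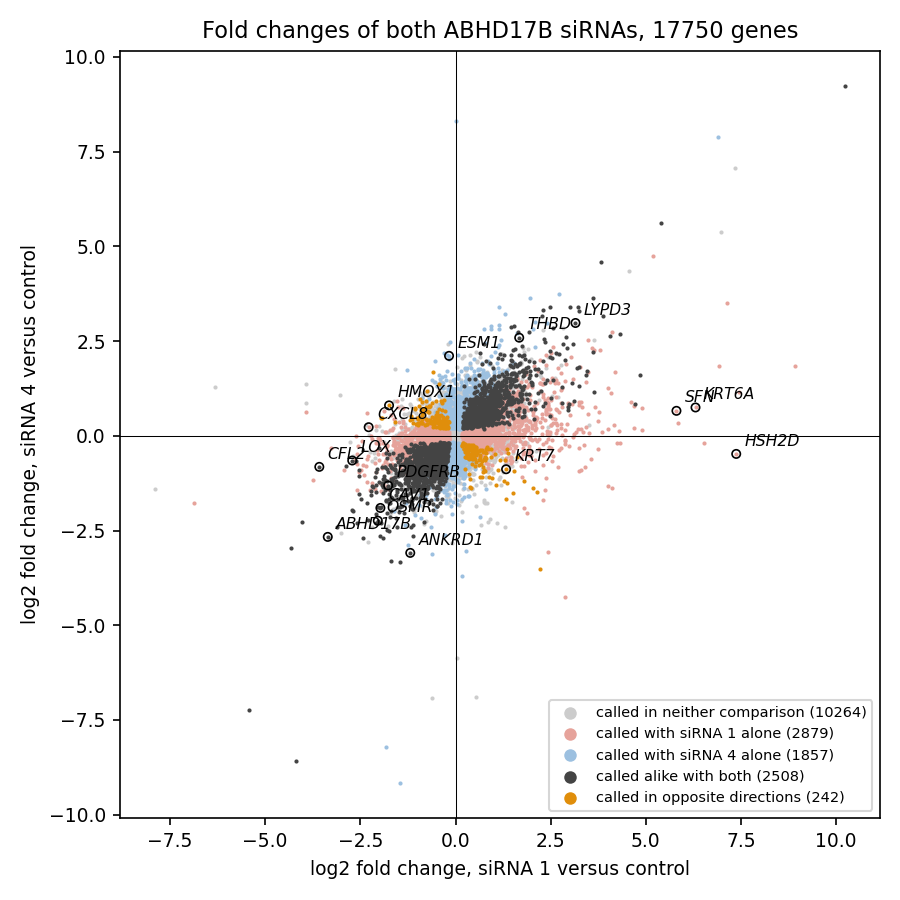
Log2 fold change with siRNA 1 (x axis) against that with siRNA 4 (y axis), each versus the control, for 17750 genes. Dark grey points are the 2508 genes called alike, orange points the 242 called in opposite directions, pink and blue points those called with siRNA 1 or siRNA 4 alone, and circles mark named genes.

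Cell division genes fell with both siRNAs, and they alone of the fixed lists kept a set call with an estimated correlation. G2/M and mitosis genes were 0 of 34 higher and 34 lower with siRNA 1, and 0 higher and 29 lower with siRNA 4. The G2/M set had adjusted p = 1.44e-20 and 7.16e-18, and adjusted p = 0.0186 and 0.0470 with an estimated correlation. G2/M genes adjusted over the list alone were 0 higher and 34 lower with siRNA 1, and 0 and 33 with siRNA 4. Their median log2 fold changes were -1.04 and -0.84. ANLN, a scaffold of the cleavage furrow, had -1.57 ± 0.095 and -0.97 ± 0.093, and the topoisomerase TOP2A -1.18 ± 0.081 and -0.89 ± 0.080. DNA replication and G1/S genes were 0 of 34 higher and 26 lower with siRNA 1, and 0 higher and 19 lower with siRNA 4. The G1/S set had adjusted p = 8.85e-13 and 1.19e-06, and adjusted p = 0.0152 and 0.0470 with an estimated correlation. G1/S genes adjusted over the list alone were 0 higher and 28 lower with siRNA 1, and 0 and 20 with siRNA 4. The thymidine kinase TK1 had -1.05 ± 0.12 and -0.86 ± 0.12. Replication-dependent histone genes were 9 of 13 higher and 0 lower with siRNA 1, and 5 higher and 0 lower with siRNA 4. The histone set had adjusted p = 1.25e-05 and 0.00361, and adjusted p = 0.0952 and 0.244 with an estimated correlation. Histone genes adjusted over the list alone were 9 higher and 0 lower with siRNA 1, and 5 and 0 with siRNA 4. H2AC6 had 1.46 and 0.91. The poly(A)-selected libraries capture transcripts with a poly(A) tail, so histone mRNA without a tail was not measured.

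Contractile genes were lower with both siRNAs. The contractile set had adjusted p = 3.06e-06 and 1.79e-05, and adjusted p = 0.0732 and 0.104 with an estimated correlation. Smooth muscle contractile genes were 0 of 20 higher and 16 lower with siRNA 1, and 1 higher and 12 lower with siRNA 4. Contractile genes adjusted over the list alone were 1 higher and 16 lower with siRNA 1, and 1 and 12 with siRNA 4. ACTA2 fell by 1.30 and 1.18 on the log2 scale, and the actin-binding CALD1 fell by 0.69 and 0.86. MYOCD, the coactivator that drives smooth muscle genes, fell by 1.55 and 1.49, and TAGLN, another actin-binding protein, fell by 0.39 and 0.71. Targets of YAP/TAZ and of serum response factor, which read out cell tension, were 1 of 27 higher and 17 lower with siRNA 1, and 3 higher and 19 lower with siRNA 4. The YAP/TAZ set had adjusted p = 2.11e-05 and 1.28e-07, and adjusted p = 0.341 and 0.244 with an estimated correlation. YAP/TAZ targets adjusted over the list alone were 2 higher and 18 lower with siRNA 1, and 3 and 19 with siRNA 4. AMOTL2 had -1.02 and -1.14. CCN2, the connective tissue growth factor, had -0.27 ± 0.074 with siRNA 1 and fell by 0.94 with siRNA 4. Its call with siRNA 1 ended without siRNA 1 replicate 1 (adjusted p = 0.0629) or control replicate 2 (adjusted p = 0.0664). Integrins and focal adhesion genes were 3 of 27 higher and 13 lower with siRNA 1, and 2 higher and 13 lower with siRNA 4. The integrin set had adjusted p = 0.00187 and 0.000949, and adjusted p = 0.283 and 0.244 with an estimated correlation. Integrin genes adjusted over the list alone were 3 higher and 14 lower with siRNA 1, and 3 and 16 with siRNA 4. The integrin ITGA4 had -1.72 and -1.78.

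Genes of the extracellular matrix fell in part. The glycoprotein set had adjusted p = 4.70e-05 and 0.00307, and adjusted p = 0.0952 and 0.242 with an estimated correlation. Matrix glycoproteins and proteoglycans were 1 of 32 higher and 18 lower with siRNA 1, and 3 higher and 12 lower with siRNA 4. Glycoprotein genes adjusted over the list alone were 2 higher and 19 lower with siRNA 1, and 3 and 14 with siRNA 4. Tenascin C (TNC) had -2.09 ± 0.11 and -1.30 ± 0.11. FN1 had -0.16 ± 0.12 and -0.26 ± 0.12, with adjusted p values of 0.368 and 0.140. Genes of collagen processing and cross-linking were 3 of 27 higher and 12 lower with siRNA 1, and 2 higher and 12 lower with siRNA 4. The collagen processing set had adjusted p = 0.00437 and 0.00281, and adjusted p = 0.525 and 0.466 with an estimated correlation. Collagen processing genes adjusted over the list alone were 3 higher and 14 lower with siRNA 1, and 3 and 12 with siRNA 4. Under upper-quartile scaling 5 of them were higher with siRNA 4. The collagen chaperone SERPINH1 fell by 1.79 and 0.60, LOXL1 fell by 0.96 and 1.43, and LOX fell by 2.71 and 0.65.

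The fibrillar collagens COL1A1 and COL3A1 fell by 0.42 and 0.30 with siRNA 1 and by 0.76 and 0.78 with siRNA 4. COL1A2 had -0.12 ± 0.089 (adjusted p = 0.348) and -0.31 ± 0.089 (adjusted p = 0.0223), the second being lost without siRNA 4 replicate 1 or 2 or control replicate 1 or 3, with an adjusted p of 0.0561 to 0.0984. Matrix-degrading enzymes and their inhibitors were 4 of 20 higher and 8 lower with siRNA 1, and 6 higher and 4 lower with siRNA 4. The matrix-degrading set had adjusted p = 0.211 and 0.350. Matrix-degrading genes adjusted over the list alone were 5 higher and 8 lower with siRNA 1, and 7 and 5 with siRNA 4. The collagenase MMP14 rose by 0.58 and 0.68, and the inhibitor TIMP3 fell by 1.65 and 1.28. TIMP1 had -0.08 ± 0.071 (adjusted p = 0.410) and rose by 0.29 ± 0.071 with siRNA 4. PDGFRB fell by 1.31 with siRNA 4.

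**Figure D3:**
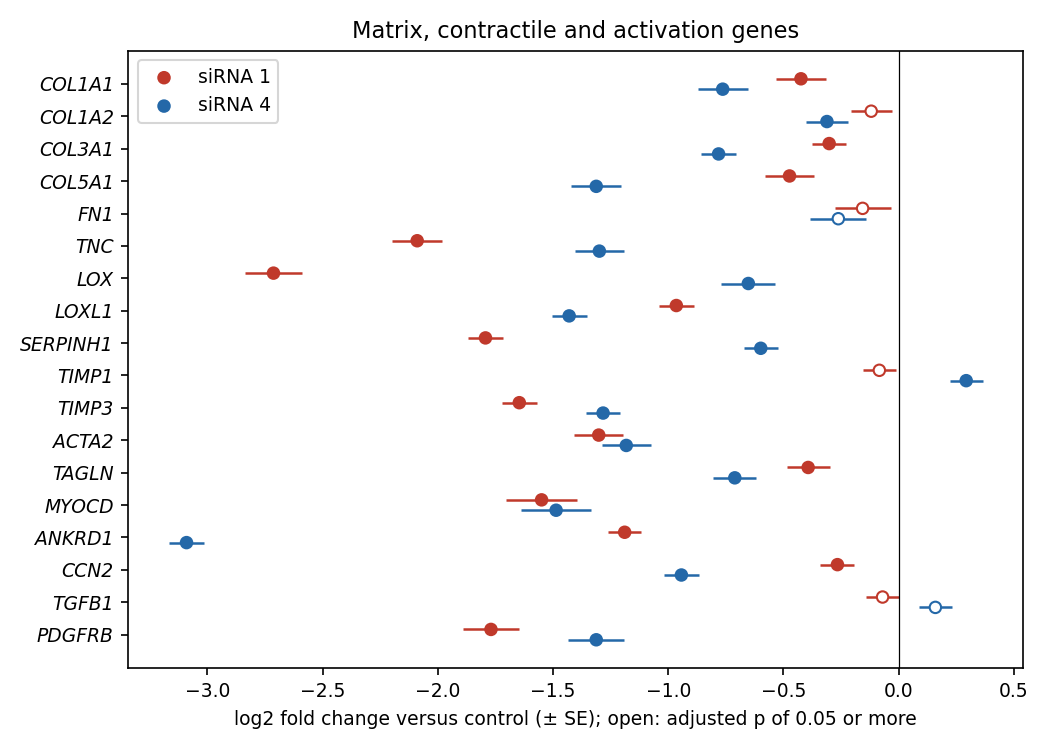
Log2 fold change (x axis, error bars SE, n = 3 per group) of matrix, contractile and activation genes with siRNA 1 (red) and siRNA 4 (blue) versus the control. Filled points passed an adjusted p of 0.05; ACTA2 lies at -1.30 and -1.18 and LOX at -2.71 and -0.65.

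Several signalling lists went both ways. TGF-beta response genes were 10 of 26 higher and 7 lower with siRNA 1, and 7 higher and 5 lower with siRNA 4. The TGF-beta set had adjusted p = 0.799 and 0.827. TGF-beta genes adjusted over the list alone were 11 higher and 9 lower with siRNA 1, and 7 and 7 with siRNA 4. With siRNA 1 their median was 0.11 and their mean -0.01. The receptor TGFBR2 had 0.96 and 0.53, and LRRC32, which holds latent TGF-beta on the cell surface, -1.93 and -1.26. TGFB1 itself had -0.07 ± 0.073 (adjusted p = 0.516) and 0.16 ± 0.073 (adjusted p = 0.135). Genes of quiescent stellate cells and retinoid handling were 5 of 23 higher and 5 lower with siRNA 1, and 6 higher and 2 lower with siRNA 4. The quiescence set had adjusted p = 0.799 and 0.0633. Quiescence genes adjusted over the list alone were 5 higher and 5 lower with siRNA 1, and 6 and 2 with siRNA 4. Their median with siRNA 1 was -0.16 and their mean 0.04. The p53 response genes were 2 of 25 higher and 10 lower with siRNA 1, and 4 higher and 8 lower with siRNA 4. The p53 set had adjusted p = 0.184 and 0.350. p53 response genes adjusted over the list alone were 2 higher and 11 lower with siRNA 1, and 4 and 9 with siRNA 4. Under upper-quartile scaling 5 p53 response genes were lower with siRNA 4. RAS-ERK response genes were 5 of 25 higher and 7 lower with siRNA 1, and 11 higher and 6 lower with siRNA 4. The RAS-ERK set had adjusted p = 0.605 and 0.216. RAS-ERK genes adjusted over the list alone were 5 higher and 7 lower with siRNA 1, and 11 and 7 with siRNA 4. The ERK phosphatase DUSP6 had 0.90 and 1.40, and the cyclin CCND1 -0.60 and -0.46.

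Lists of protein folding, respiration and small RNA silencing followed. Unfolded protein response genes were 2 of 23 higher and 9 lower with siRNA 1, and 2 higher and 10 lower with siRNA 4. The unfolded protein set had adjusted p = 0.00750 and 0.0462, and adjusted p = 0.525 and 0.605 with an estimated correlation. Unfolded protein response genes adjusted over the list alone were 2 higher and 10 lower with siRNA 1, and 3 and 10 with siRNA 4. SEL1L, an adaptor of protein degradation at the endoplasmic reticulum, had -0.62 and -0.57. Oxidative phosphorylation genes were 5 of 36 higher and 3 lower with siRNA 1, and 3 higher and 3 lower with siRNA 4. The respiration set had adjusted p = 0.850 and 0.827. Oxidative phosphorylation genes adjusted over the list alone were 4 higher and 3 lower with siRNA 1, and 0 and 1 with siRNA 4. Genes of small RNA silencing were 1 of 13 higher and 4 lower with siRNA 1, and 2 higher and 4 lower with siRNA 4. The silencing set had adjusted p = 0.462 and 0.498. Silencing genes adjusted over the list alone were 1 higher and 5 lower with siRNA 1, and 2 and 4 with siRNA 4. AGO4 had 1.33 and 1.06. Mesothelial and portal fibroblast markers were 0 of 10 higher and 5 lower with siRNA 1, and 0 higher and 4 lower with siRNA 4. The mesothelial set had adjusted p = 0.00857 and 0.00881, and adjusted p = 0.118 and 0.141 with an estimated correlation. Members of that list adjusted over the list alone were 0 higher and 7 lower with siRNA 1, and 0 and 4 with siRNA 4. Their summed levels were 2889 ± 178, 3865 ± 117 and 4899 ± 92.4 CPM with siRNA 1, with siRNA 4 and in the control. Most of the control sum came from GREM1 (2386 CPM), FBLN2 (1338.5) and THY1 (925). MSLN (0.299) and CALB2 (1.70), like FBLN2 chosen after their values were seen, lay far lower, and MSLN had 0.565 CPM with siRNA 1. The sums and the set call therefore say little about mesothelial cells. THY1, a surface protein of fibroblasts in that list, fell by 0.91 and 0.69.

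The remaining lists stayed without a set call in 1 of the comparisons. Of cholesterol synthesis genes, 5 of 26 were higher and 1 lower with siRNA 1 (set adjusted p = 0.213). Under upper-quartile scaling 10 were higher and 1 lower. Sterol genes adjusted over the list alone were 4 higher and 1 lower. Of fatty acid and lipid droplet genes, 7 of 30 were higher and 11 lower with siRNA 1 (set adjusted p = 0.429). Fatty acid genes adjusted over the list alone were 7 higher and 11 lower. Of lysosome and autophagy genes, 7 of 30 were higher and 5 lower with siRNA 1 (set adjusted p = 0.658). Lysosome genes adjusted over the list alone were 7 higher and 6 lower. Of hypoxia and glycolysis genes, 3 of 30 were higher and 10 lower with siRNA 1 (set adjusted p = 0.133). Hypoxia genes adjusted over the list alone were 3 higher and 10 lower. Of integrated stress response genes, 3 of 24 were higher and 7 lower with siRNA 1 (set adjusted p = 0.327). Stress response genes adjusted over the list alone were 3 higher and 7 lower. Of interferon response genes, 3 of 39 were higher and 5 lower with siRNA 4 (set adjusted p = 0.350). Interferon genes adjusted over the list alone were 2 higher and 5 lower. Of complement and antigen presentation genes, 4 of 23 were higher and 1 lower with siRNA 4 (set adjusted p = 0.382). Complement and antigen genes adjusted over the list alone were 4 higher and 1 lower. Of inflammatory genes, 11 of 31 were higher and 5 lower with siRNA 4 (set adjusted p = 0.548). Inflammatory genes adjusted over the list alone were 12 higher and 6 lower. Of senescence genes, 6 of 19 were higher and 6 lower with siRNA 4 (set adjusted p = 0.839). Senescence genes adjusted over the list alone were 7 higher and 7 lower. Of growth factor receptors, 3 of 25 were higher and 7 lower with siRNA 4 (set adjusted p = 0.221). Receptor genes adjusted over the list alone were 3 higher and 8 lower. Of ribosomal protein genes, 0 of 41 were higher and 1 lower with siRNA 4 (set adjusted p = 0.548). Ribosomal genes adjusted over the list alone were 0 higher and 0 lower. Of mitochondrially encoded genes, 0 of 13 were higher and 3 lower with siRNA 4 (set adjusted p = 0.0565). Mitochondrial genes adjusted over the list alone were 0 higher and 3 lower. Of the 35 lists tested, 18 were called with siRNA 1, 17 with siRNA 4 and 21 with both siRNAs together. Of these, 2, 2 and 2 held with an estimated correlation.

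**Figure D4:**
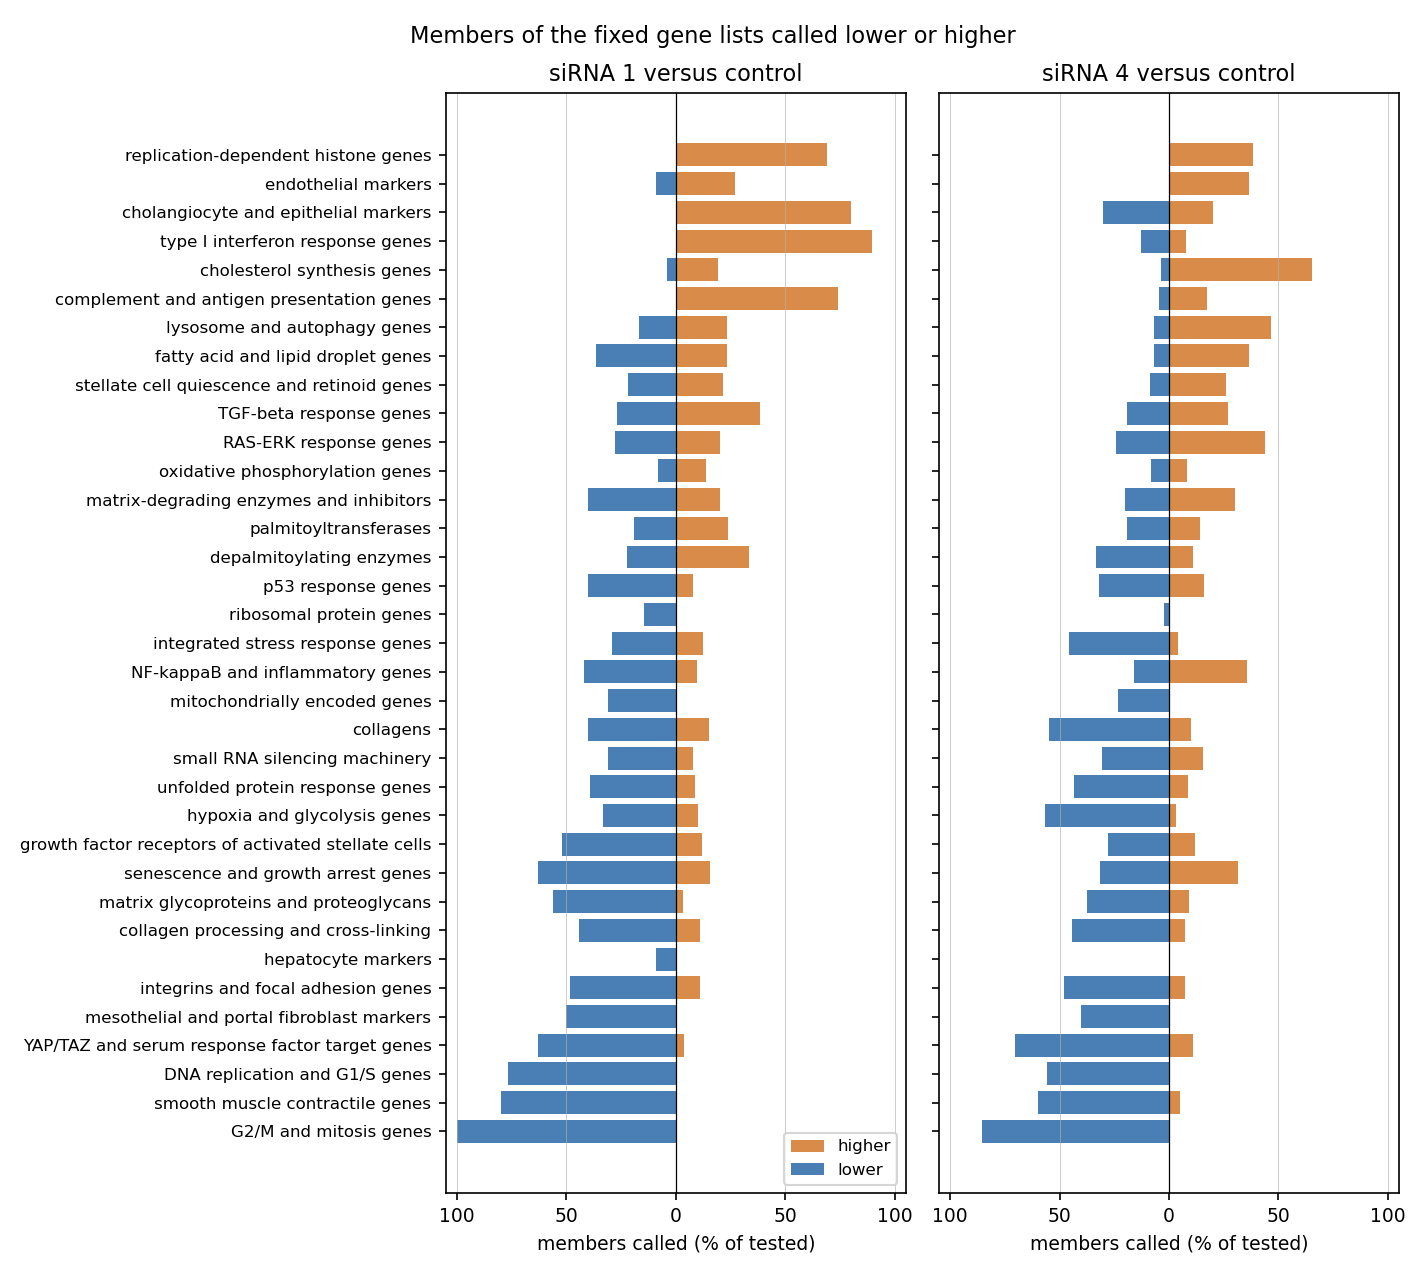
Share of the tested members of each fixed gene list (x axis, percent) called higher (orange) or lower (blue) with siRNA 1 (left) and siRNA 4 (right) versus the control. All 34 G2/M and mitosis genes were lower with siRNA 1 and 29 with siRNA 4, while 35 of 39 interferon response genes were higher with siRNA 1 and 3 with siRNA 4.

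siRNA 1 against siRNA 4 tested the difference between reagents that share a stated target. Interferon response genes were higher with siRNA 1 than with siRNA 4. The interferon set had adjusted p = 7.71e-20, and adjusted p = 0.224 with an estimated correlation. Of its genes, 38 of 39 were higher and 0 lower with siRNA 1 than with siRNA 4. Interferon genes adjusted over the list alone were 39 higher and 0 lower. Of cholesterol synthesis genes, 0 of 26 were higher and 16 lower with siRNA 1 than with siRNA 4. The sterol set had adjusted p = 2.80e-06, and adjusted p = 0.359 with an estimated correlation. Sterol genes adjusted over the list alone were 0 higher and 17 lower. Of the genes with the highest fold changes, HSH2D had 1037 counts with siRNA 1 and 4 with siRNA 4. KRT6A, SFN, SPINT1 and FBXO2 differed by 5.56 ± 0.27, 5.14 ± 0.19, 4.74 ± 0.30 and 4.42 ± 0.37. The lowest were CFL2 (-2.76 ± 0.078), NPTX1 (-2.61 ± 0.34), OSTM1 (-2.60 ± 0.092), the heme oxygenase HMOX1 (-2.55 ± 0.12) and CXCL8 (-2.51 ± 0.083). HMOX1 fell by 1.75 with siRNA 1 and rose by 0.80 ± 0.11 with siRNA 4.

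Between the siRNAs 4301 genes differed, 2194 higher and 2107 lower with siRNA 1, of which 563 and 383 differed at least 2-fold, and the groups did not overlap in 7035 genes, where chance separates 10%. More were lower than higher under upper-quartile scaling (2064 higher, 2213 lower) and without siRNA 4 replicate 2 (1631 higher, 1663 lower). Of the 2879 genes called with siRNA 1 alone, 1673 differed between the siRNAs, and of the 1857 called with siRNA 4 alone, 1026 did, while 704 of the 2508 genes changed alike differed in size. CAGTATT stood in the 3′ UTRs of 32.8% of the searched genes that were lower with siRNA 1 than with siRNA 4 and of 13.7% of those higher. The word was picked from fold changes of the same siRNA 1 samples, so these shares are no separate support. They are also not corrected for length, with median 3′ UTRs of 1822 nt in the lower and 1365 nt in the higher genes.

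The set test called 15 lists between the siRNAs, and camera with an estimated correlation called 0. Of inflammatory genes, 1 of 31 were higher and 19 lower with siRNA 1 than with siRNA 4. The inflammatory set had adjusted p = 3.36e-07, and adjusted p = 0.170 with an estimated correlation. Inflammatory genes adjusted over the list alone were 2 higher and 19 lower. Of matrix-degrading enzymes and inhibitors, 1 of 20 were higher and 10 lower with siRNA 1 than with siRNA 4. The matrix-degrading set had adjusted p = 0.000131, and adjusted p = 0.129 with an estimated correlation. Matrix-degrading genes adjusted over the list alone were 1 higher and 11 lower. TIMP2 had -0.65. Of epithelial markers, 6 of 10 were higher and 0 lower with siRNA 1 than with siRNA 4. The epithelial set had adjusted p = 3.86e-05, and adjusted p = 0.0768 with an estimated correlation. Epithelial markers adjusted over the list alone were 6 higher and 0 lower. KRT7 had 2.21 ± 0.086, after calls of 1.33 with siRNA 1 and -0.88 with siRNA 4. Of collagens, 9 of 20 were higher and 1 lower with siRNA 1 than with siRNA 4. The collagen set had adjusted p = 0.0365, and adjusted p = 0.633 with an estimated correlation. Collagens adjusted over the list alone were 9 higher and 2 lower. COL5A1 had 0.84 ± 0.11 and COL3A1 0.48 ± 0.075. Of G1/S genes, 0 of 34 were higher and 13 lower with siRNA 1 than with siRNA 4. The G1/S set had adjusted p = 8.75e-05, and adjusted p = 0.0768 with an estimated correlation. G1/S genes adjusted over the list alone were 0 higher and 14 lower. Of G2/M genes, 1 of 34 were higher and 14 lower with siRNA 1 than with siRNA 4. The G2/M set had adjusted p = 0.000112, and adjusted p = 0.224 with an estimated correlation. G2/M genes adjusted over the list alone were 1 higher and 15 lower.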

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

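Several tests in this part were chosen only after the result was seen. These were the ratio of z values for siRNA 4 against the control, the search for its word in the target and site numbers against the control. Sites in the coding sequence, the test of epithelial cells, the test of E-box words and all counts of other splits were too. The other tests in this part were set before their own result was seen, and only this is meant by planned here. All tests on words came after the data had been examined, and the words were picked from these fold changes. The results below stand out because the siRNAs, aimed at the same mRNA, differed from each other by a test of the difference itself.

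Type I interferon response genes were higher with siRNA 1 than with siRNA 4 (adjusted p = 7.71e-20). Inflammatory genes (3.36e-07), cholesterol synthesis genes (2.80e-06), senescence genes (0.000112), matrix-degrading enzymes and inhibitors (0.000131) and fatty acid and lipid droplet genes (0.000335) also differed. So did epithelial markers (3.86e-05), G1/S genes (8.75e-05), G2/M genes (0.000112), complement and antigen presentation genes (0.000121) and histone genes (0.00362). RAS-ERK response genes (0.00888), lysosome and autophagy genes (0.0118), integrated stress response genes (0.0306) and collagens (0.0365) passed as well. With an estimated correlation, camera called 0 of these 15 lists, while fry, which does not compare a list with other genes, called 23 of the 35 tested. HMOX1 (-2.55), SPP1 (1.83) and KRT7 (2.21), as log2 differences of siRNA 1 from siRNA 4, were among 242 genes called in opposite directions against the control.

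The first pattern is that many genes were lower with one siRNA than with the other. In genes lower with siRNA 1, the z of the strongest 3′ UTR word, CAGTATT, was 2.08 times that of the strongest word for higher expression and the word occurs in 2 of 2 protein-coding ABHD17B transcripts, consistent with repression through seed matches of siRNA 1, although 15.3% of all 7-base words occur there and the siRNA sequences are not given in the sources used here. Genes with 2 or more CAGTATT sites differed from genes with 1 by a median log2 value of -0.0630 (SE 0.0199) between the siRNAs, the planned test, and against the control by -0.0480 (SE 0.0262), or with 3 or more sites by -0.148 (SE 0.0496), consistent with repression that grows with the number of sites of siRNA 1. CAGTATT is also a microRNA seed match, as given in the last pattern, so these values do not separate siRNA 1 from such microRNAs. For TCCTGAT the planned value was 0.0944 (SE 0.0266), but against the control it was -0.0081 (SE 0.0372) with siRNA 4, or -0.101 (SE 0.0524) with 3 or more sites, and 0.0562 (SE 0.0378) with siRNA 1, so that growth with the number of sites stays open for siRNA 4. The planned ratio of z values for siRNA 4 was 0.481, under its bound of 1.5, but that bound was wrong for this contrast because its denominator is the word of siRNA 1 itself, and a ratio of 1.82 against the control, TCCTGAT in 2 of 2 ABHD17B transcripts and its z of 4.50 between the siRNAs, where the strongest word for higher expression, CCTGATG (4.51), is TCCTGAT moved by 1 base, are consistent with repression through seed matches of siRNA 4.

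The second pattern is the set of genes changed alike by both siRNAs. Of the searched genes lower with both, 42.7% held CAGTATT or TCCTGAT in the 3′ UTR against 28.0% of all searched genes, which argues against direct 3′ UTR sites as the whole cause. These shares are not corrected for 3′ UTR length, which had medians of 1718.5 nt and 1384 nt. In the coding sequence TCCTGAT had a z of -5.54 with siRNA 4 and CAGTATT of -3.80 with siRNA 1. Of the genes lower with both, 59.8% held either word in the 3′ UTR or the coding sequence against 41.8% of all. This lies between the bounds of 50% and 90%, which leaves that test, chosen after the result was seen, undecided. Direct sites alone would however need a site of each siRNA in a gene, and 40.2% of these genes held neither word. That share argues against direct sites of these words in these regions as the whole cause, while a part and indirect effects of sites stay open. Of those higher with both, 11.8% held TGACTAA against 9.76% of all, which argues against repression by the control siRNA as the whole cause. TGACTAA was picked as the word whose smaller z of both comparisons with the control was highest. That choice favours a z near 0 between the siRNAs, so its z of 1.46 there decides nothing. Repression by the control siRNA, but also a shared effect of the ABHD17B siRNAs, would give such a value. Genes with 2 or more TGACTAA sites differed from genes with 1 by a median log2 value of -0.005 (SE 0.0514) with siRNA 1. With siRNA 4 the difference was -0.0045 (SE 0.0433), so growth with the number of sites was not seen. Loss of ABHD17B may account for part of the shared changes, which no rescue or further siRNA in these data can test.

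The last pattern is the rise of epithelial markers with siRNA 1, for which epithelial cells in those cultures cannot be told apart from a change within the stellate cells, because no value here decides. Of 17 tested genes on an epithelial check list 70.6% were higher, but that list was written after values were seen and 9 of the 17 were fixed epithelial markers or genes with the highest fold changes, so this share says nothing. KRT14, named as a sign against such cells, was lower with siRNA 1 (-1.13) but also with siRNA 4 (-0.95, with an adjusted p of 0.435 between the siRNAs). Of genes named after their values were seen, CLDN4 had 198 counts with siRNA 1 against 190 in the control. EPCAM (64 against 21), CLDN7 (82 against 24), S100A14 (62 against 4), KRT5 (21 against 8) and RAB25 (9 against 1) had more counts with siRNA 1 but lie near the floor. Of these, CLDN7 (adjusted p = 0.0449) and S100A14 (adjusted p = 0.00633) passed in edgeR's quasi-likelihood test. A candidate explanation is low ZEB1 and ZEB2, repressors of epithelial genes, named here after their values were seen (-1.83 and -1.93 with siRNA 1). Both are known targets of miR-200b and miR-200c, whose seed match is also CAGTATT, and they hold 6 and 5 sites of it. Words with the E-box that they bind reached a z of 5.98 for higher expression in 5′ UTRs with siRNA 1, but GCCGCCG reached -5.97 for lower expression, and between the siRNAs such a word reached 4.85, under the bound of 5 and below CCTACCT (5.82), so this test leaves the release of such genes open.

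Other splits of the samples into groups of the same sizes were counted. For siRNA 1, siRNA 4 and the difference between them the real counts of genes were 5629, 4607 and 4301, the highest other count was 0 for each by edgeR, and 1, 1 and 1 of 10 splits gave as many. For gene lists in the same comparisons the real counts were 18, 17 and 15, the highest others 18, 15 and 9, and 2, 1 and 1 of 10 splits gave as many. In both cases 10 splits are too few for a share under 0.05. For both siRNAs together (5515 genes, highest other 2555) and for genes changed alike (2508, highest other 1210), 1 of 100 splits gave as many. Splits that mix the groups put the differences between groups into the spread within groups, which lowers their counts. The split with 1210 genes alike kept the control samples together. These shares lie under 0.05 but for that reason cannot exclude chance. For the 21 lists called with both together 3 of 100 splits gave as many, and the highest other split called 23. That share also lies under the bound of 0.05, but it has the same limit. The 100 splits were drawn from 840 possible ones with the real one included, so this share is an estimate and not a firm exclusion.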

How the results depend on the processing

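All alternatives below were planned and none was chosen after the result was seen. Of 609 results of 203 named genes, 474 were called; 370 of these kept their call under every alternative that gave them a value, 104 lost it under at least 1, and 0 reversed. The difference of ABHD17B between the siRNAs had an adjusted p of 0.0332 to 0.170 over the alternatives. A test against a fold of 1.2 called 3083 genes with siRNA 1, 2244 with siRNA 4, 2522 with both together, 2097 between the siRNAs and 1077 alike. An adjusted p of 0.01 called 3541, 2700, 3407, 2511 and 1372, and a fold of 2 with both siRNAs left 346 alike. These are stricter by construction. Leaving out 1 sample gave 4567 to 5544, 3498 to 5099, 4225 to 5633, 3208 to 4223 and 1946 to 2564 genes in the same order, and 16 to 18, 15 to 19, 16 to 24 and 14 to 19 gene lists. With an estimated correlation 2, 2, 2 and 0 lists were called, which allows for genes that move together, and fry called 23 between the siRNAs, which does not compare a list with other genes. The covariance of fold changes was 0.250 to 0.263 without 1 siRNA-treated sample. Without 1 control sample it was 0.325 to 0.333, with 0.333 for control replicate 1. All of these lie above the 0.234 of the full data, and the jackknife SE of 0.0969 includes this difference between treated and control samples. Genes were filtered anew in each of these fits, which held 18163 to 18300 genes against 17750. The SE is therefore not a plain measure of the spread of 0.234. With a filter of 1 CPM in 3 samples the covariance was 0.158 (the cause was not tested). With replicate number as a block the counts of genes were 6074, 5000, 5957, 4710 and 2799. These numbers, from the sample titles, differ from those in the names of the deposited files, and what they mark is not given. The deviations of 2 of 9 pairs with the same number correlated above 0.1, and all pairs ran from -0.0407 to 0.126. However, 6 of 9 samples correlated best with their own number, a hint from the data and not the design. Whether equal numbers mark paired samples therefore stays open. Upper-quartile scaling moved the median fold change of all genes by up to 0.051 and turned the balance of higher and lower genes in each of the 5 counts. DESeq2 gave 11, 700, 11 and 11 genes no adjusted p with siRNA 1, with siRNA 4, with both and between the siRNAs (the cause was not tested). Depth limits which genes can be tested: of 33039 with a count, 17750 passed the count filter.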

Other observations

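The test of genes without siRNA words, given here for the lists of cell division, contraction and matrix synthesis, was chosen only after the result was seen. Of genes with neither CAGTATT nor TCCTGAT in the 3′ UTR, 29 of 29 G2/M and mitosis genes were lower with siRNA 1 and 24 with siRNA 4, 19 and 14 of 26 G1/S genes, and 12 and 10 of 15 contractile genes. The same held for 9 and 7 of 20 matrix glycoproteins and proteoglycans, 6 and 9 of 18 collagens and 7 and 7 of 21 collagen processing genes. Of genes with either word, 5 and 5 of 5 G2/M genes, 7 and 5 of 8 G1/S genes, 4 and 2 of 5 contractile genes, 9 and 5 of 12 glycoproteins, 2 and 2 of 2 collagens and 5 and 5 of 6 collagen processing genes were lower. Collagen processing genes had median log2 fold changes of -1.34 and -0.60 with a word and of -0.08 and -0.10 without. The split of other lists is not given in full, and in some the fall lay mainly with the words. Palmitoyltransferases were lower in 4 and 3 of 8 genes with either word and in 0 and 1 of 13 with neither.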
